A study of Mus musculus with 6 samples.

How the data were processed

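Single-cell RNA sequencing had been run on cultured colonic mesenchymal cells of 6 mice, 3 labelled control, whose genotype per the labels is heterozygous for the gene of tumour necrosis factor (TNF) receptor 1, and 3 labelled TNFR1_KO, whose genotype is homozygous for its loss. Per the labels' protocols, primary colonic myofibroblasts came from the distal colon of 16-week-old mice, were grown in Matrigel in medium with serum and EGF, were taken 5 days after passage, passed a dead cell removal step, and were made into 10X Chromium 3' libraries. The submitters' processing notes name Cell Ranger 5.0.0 and the mm10 build. The annotation, the filter on cells and the way clusters were made are not given in the sources used here, nor are the sex of the mice, the deleted part of the gene and any batch.

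The deposited matrix held whole-number UMI counts of 30360 genes in 34415 cells, with 954228864 UMIs in 148781090 nonzero entries. A row for EGFP was at 0 in every cell, and 34 gene symbols stood on more than 1 row, so genes were handled by identifier. The deposited cell table gave another kind of value, the sample name and a cluster number from 1 to 6 without a cell type name, and 2 kinds of score by the authors, a size factor and the coordinates of an embedding. The deposited score named size factor was proportional to each cell's UMI total within a relative deviation of 5.1e-15, and it was not used further. Cells were assigned to mice by the deposited sample name, and 136 barcodes occurred on more than 1 cell. Every cell was kept. Gene positions came from GENCODE M21 on the same build, which held 30240 of the genes and lacked 120.

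Cells are not replicates, so raw counts were summed per mouse. Genes between genotypes were tested with edgeR 4.0.16 (filterByExpr, TMM, quasi-likelihood test, two-sided, Benjamini-Hochberg adjusted p under 0.05, referred to as called). Levels are given as normalised CPM, UMI counts scaled by library total and by the TMM factors, as mean ± SD over 3 mice per genotype, and every log2 fold change is TNFR1_KO over control. The 34 gene lists, fixed with the other choices of design, were tested with camera in limma 3.58.1 at a preset correlation of 0.01 and adjusted over the lists. Camera was repeated with an estimated correlation, and fry, which tests whether a list moves on balance 1 way without comparing it with other genes, was run beside it. The 16 marker lists of cell types were used only to count markers. Shares of the deposited clusters were tested with edgeR on cell numbers and with two-sided exact permutation tests, whose smallest p with 3 mice against 3 is 0.1. The same gene test was run within deposited clusters with at least 20 cells in each mouse, which left cluster 2. Every alternative clustering used scanpy 1.11.5 with 2000 variable genes, 30 principal components and 15 neighbours, under Python 3.11.15 and R 4.3.3.

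The rule for named genes took the targeted gene first, then the 10 genes with the largest log2 fold change in each direction among the 5051 genes that were called, did not overlap between genotypes and had a mean of at least 10 CPM, leaving out names of predicted genes. It then took up to 4 called members of each list by adjusted p, the 3 genes with the smallest adjusted p in each direction within a cluster, and the 5 leading genes of each cluster. A gene named outside that rule, to spell out a count of 5 or fewer, to give markers, or to show list members, was chosen after its values were seen. A few genes that the rule or a count would name are not reported here. Genes at 0 in 1 genotype are given as a bound at a floor of 3 UMIs summed over that group.

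Total UMIs per mouse lay between 119132056 and 182499766. Intervals of shares are 95% Wilson intervals, and these and the floors cover counting error only. On simulated counts of 14779 genes with the means and library sizes of the comparison of all cells, the test recovered 15 of 50 genes changed 1.2-fold, 49 of 50 changed 1.5-fold, 49 of 50 changed 2-fold and 50 of 50 changed 4-fold, with 12 calls among 14579 unchanged genes. Few genes were changed in the simulation, evenly in both directions and all with a mean of at least 1 CPM, and its samples were independent. It says nothing about recovery at lower levels, or about errors where most genes differ or where cultures were not separate. No pair of libraries differed by random sampling of UMIs alone: chi-square per degree of freedom over genes was 14.8 to 28.0 between controls and 45.0 to 157 between TNFR1_KO mice. Repeat samples of 1 culture are not excluded by these values, since cells are sampled too. The median absolute log2 ratio was 0.0637 to 0.0782 between controls, 0.106 to 0.213 between TNFR1_KO mice, and 0.412 to 0.446 between genotypes. The filter on genes was looser between genotypes and let in genes with few UMIs in 1 of the libraries, so that range is not strictly comparable. Nothing in the labels says whether each culture was started and handled separately, so p-values measure the spread between these samples, which may be partly technical.

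Alternatives covered other size factors, DESeq2 1.42.0 in place of edgeR, limma-voom, filters on genes and cells, equal library totals and equal cell numbers. They also covered scaling of each cell, other clusterings and each mouse left out. Phase calls and shares of cells with a UMI were repeated after each cell was thinned to 5000 UMIs. Scrublet marked 1 of 34415 cells, so doublets were in effect not removed. A difference of the genotype effect between the most abundant clusters could not be fitted, because cluster 1 held no control cell.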

Results

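The data were single-cell transcriptomes of myofibroblasts cultured from the distal colon of 3 control mice, heterozygous for the TNF receptor 1 gene, and 3 TNFR1_KO mice, which lack it per the labels. The question of the series is what TNF receptor 1 signalling does in the colonic mesenchyme and in its exchange with the epithelial stem cell niche. The control mice gave 5139, 5613 and 5844 cells with 119132056, 154003299 and 176302177 UMIs. The TNFR1_KO mice gave 6757, 5431 and 5631 cells with 182499766, 157408615 and 164882951 UMIs. The median cell held 26345 ± 2967 UMIs in controls and 28277 ± 1346 in TNFR1_KO (SD, n = 3 mice per genotype). Every mean ± SD below is over 3 mice per genotype, and levels are in normalised CPM unless another unit is named.

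Tnfrsf1a, which encodes the receptor (ENSMUSG00000030341, chromosome 6, 125349362 to 125362484, mm10), was at 58.5, 62.7 and 58.0 normalised CPM in the control mice and at 11.8, 11.5 and 11.5 in the TNFR1_KO mice. The means were 59.7 ± 2.6 and 11.6 ± 0.16 (log2 fold change -2.37, SE 0.06, edgeR adjusted p = 1.90e-11), a level 5.16-fold lower. Against control cluster 6 alone, a comparison chosen after the data were seen, the log2 fold change was smaller (-1.46). Which part of the gene was deleted is not given, and a 3' tag outside that part checks nothing about the allele. A UMI of Tnfrsf1a was seen in 55.9% (95% Wilson interval 54.6 to 57.3), 58.6% (57.4 to 59.9) and 58% (56.7 to 59.3) of control cells and in 24.2% (23.2 to 25.2), 26.5% (25.3 to 27.7) and 25.4% (24.3 to 26.5) of TNFR1_KO cells. After thinning to 5000 UMIs the shares were 23.7% ± 0.39 and 5.31% ± 0.27, with 3358 control and 1884 TNFR1_KO cells left out. No cell type that lacks the gene was available to measure free RNA. Tnfrsf1b, the other TNF receptor, was slightly lower (log2 fold change -0.30, adjusted p = 0.0017). Tnf itself gave 3, 0 and 1 UMIs in the control mice and 0, 1 and 0 in the TNFR1_KO mice.

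Across all cells, TNFR1_KO cultures differed from control cultures in most genes that could be tested. Rpl39l, a paralog of a ribosomal protein gene, had no UMI in any control mouse and 137 ± 9.2 CPM in TNFR1_KO, at least 20532-fold higher. Meg3, a maternally expressed long noncoding RNA, rose from 0.665 ± 0.078 to 114 ± 33 (log2 fold change 7.41). Mfap2, a microfibril protein gene, rose by 10.23 on the log2 scale to 29.6 ± 5.7, and the growth factor gene Igf1 rose from 1.04 ± 0.065 to 19.5 ± 0.80 (4.22). In the other direction, Isg15, a ubiquitin-like protein induced by interferon, fell from 189 ± 8.4 to 7.28 ± 0.52 (-4.70), and Ripk3, a kinase of necroptosis, fell from 53.2 ± 0.51 to 3.72 ± 0.85 (-3.84). Other increases taken by the rule were Asb5 (8.23), Vax2 (7.22), Smoc2 (4.84), Plxdc2 (3.88) and Cspg4 (3.83). The other decreases were Smim20 (-7.45), Glipr1 (-7.18), Slfn2 (-5.28), Angptl4 (-4.43), the lactate transporter Slc16a3 (-4.35), Apol9b (-3.99), Usp18 (-3.97) and Phf11d (-3.82). Slc16a3 was concentrated in control cluster 5, at 112 raw CPM against 13.2 in all other cells. edgeR called 5253 genes higher and 5209 lower, 10462 of the 14779 tested or 70.8%, and 1507 and 1439 of these differed more than 2-fold. The values of the genotypes did not overlap for 10989 genes (74.4%), where chance gives 10%. The median log2 fold change over all genes was 0.00. TMM centres the changes near 0, so this median and the near-even split of calls largely follow from the scaling.

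**Figure D1:**
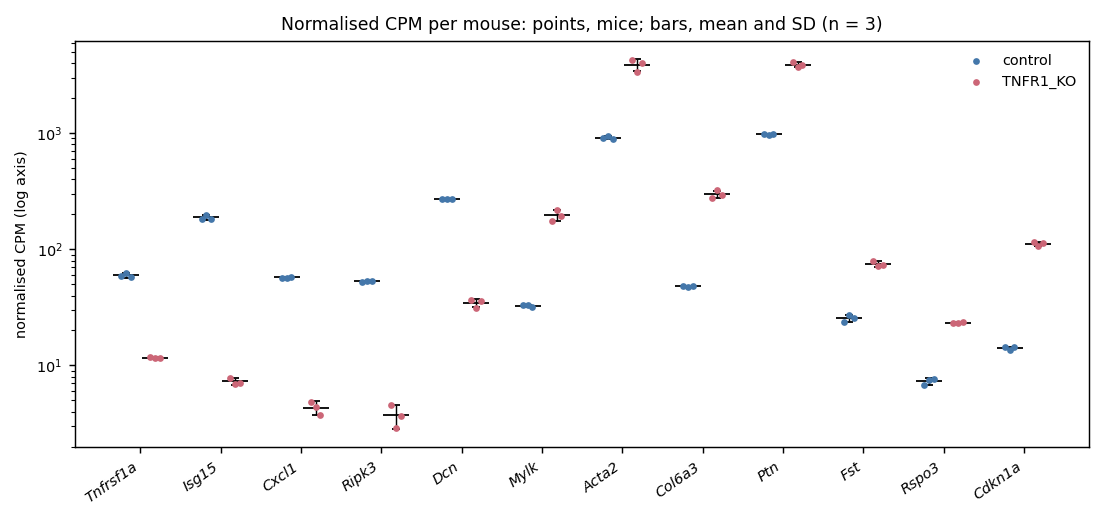
Normalised CPM on a log axis of 12 named genes, with a point for each control or TNFR1_KO mouse and bars for mean and SD (n = 3). Tnfrsf1a lies between 58.0 and 62.7 in the controls and between 11.5 and 11.8 in TNFR1_KO.

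Of the 34 gene lists, camera called 7 higher and 9 lower, fry called 28, and no list was called with an estimated correlation, whose adjusted p is given beside each call over all cells. With the estimated correlation 8 lists had an unadjusted p under 0.05, and the lowest adjusted p was 0.156. At the preset correlation camera also called up to 14 lists when the mice were split with the genotypes mixed. Such splits keep part of the genotype difference between their groups, so this is no rate of false calls. Counts of members adjusted over the list alone equalled those over all genes tested in 31 lists, and the 3 lists where they differed are named with their counts. The lists are not separate: 16 of the 33 members of the chemokine and cytokine list also stand on the TNF and NF-kB list.

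The lists closest to the receptor fell. Of 43 genes of the TNF and NF-kB response, 30 were lower, 8 higher and 5 not called, with a median log2 fold change of -0.92 (camera adjusted p = 2.78e-05, and adjusted p = 0.156 with an estimated correlation). The neutrophil chemokine genes Cxcl5 (-6.67) and Cxcl1 fell, Cxcl1 from 57.4 ± 0.59 to 4.33 ± 0.57 (-3.73), as did the signalling adaptor gene Traf1 (-4.10). Control cluster 6 carried most of the Traf1 level, at 84.9 raw CPM against 1.95 in all other cells, and Traf1 was lower by -2.67 against control cluster 3 and -1.74 against cluster 5. Cxcl16, a membrane-bound chemokine gene, went from 12.3 ± 0.42 to no UMI in any TNFR1_KO mouse, at least 2069.5-fold lower. Higher members of the same list included the adhesion molecule gene Icam1 (3.71) and Steap4 (3.98). Among 28 components of the signalling pathway itself, 21 were lower, 4 higher and 3 not called (median -0.34, camera adjusted p = 8.38e-04, adjusted p = 0.156 with an estimated correlation). Besides Tnfrsf1a and Ripk3, the lower ones included Mlkl, the effector of necroptosis (35.7 ± 1.2 to 14.5 ± 0.67, -1.30), and Tab1 (-0.95), while Traf5 (0.48), Cflar (0.35), Map3k7 (0.18) and Adam17 (0.35) were higher.

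The lists of the interferon response, MHC class I presentation and chemokines were called lower, and the interferon response had the smallest camera p of the 34. Of its 32 genes, 31 were lower and 1, Ifi27l2a (1.08), was higher, with a median of -3.03 (camera adjusted p = 5.13e-15, adjusted p = 0.168 with an estimated correlation). Besides Isg15 and Usp18, Oasl2 (-3.45) and Rtp4 (-3.47) fell, all genes induced by interferon. In the list of MHC class I presentation 13 genes were lower, among them Psmb8 of the immunoproteasome (-2.63), the class I heavy chain genes H2-K1 (37.7 ± 0.14 to 9.44 ± 0.52) and H2-Q4 (-4.90) and the proteasome activator gene Psme1 (-1.22). B2m (0.71) and H2-T23 (1.17) were higher, and the list's median was -1.29 (camera adjusted p = 2.63e-04, adjusted p = 0.391 with an estimated correlation). H2 genes have close paralogs, and UMIs shared between them could not be told apart. Of 25 chemokines and cytokines, 17 were lower, among them Ccl9 (-3.49), and 5 higher, namely Cxcl12 (1.17), Cxcl13 (6.04), Csf1 (0.74), Il11 (3.27) and Ccl8 (0.37), with 3 not called (median -2.04, camera adjusted p = 2.63e-04, adjusted p = 0.2 with an estimated correlation). The complement list was not called (5 lower, 2 higher of 7, median -0.54, adjusted p = 0.207): C3, the central complement component, fell (-3.15), as did C1qtnf6 (-0.62), C1ra (-0.54), C1s1 (-0.41) and C4b (-0.62), while C2 (1.73) was among those that rose.

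Contractile and matrix genes were higher in TNFR1_KO. Of 22 contractile and myofibroblast genes 20 were higher, 1 lower (Csrp1, -0.55) and 1 not called (Des), with a median of 0.79 (camera adjusted p = 1.49e-05, adjusted p = 0.156 with an estimated correlation). Acta2, smooth muscle actin, rose from 917 ± 29 to 3882 ± 445 (2.08), Mylk, the kinase of the myosin light chain, from 32.8 ± 0.63 to 196 ± 22 (2.58), Lmod1 by 2.26 and Tagln by 1.29. Of 20 collagen genes 17 were higher, 2 lower (Col18a1, -2.85, and Col5a3, -1.06) and 1 not called, median 1.01 (camera adjusted p = 1.41e-04, adjusted p = 0.336 with an estimated correlation). Col6a3 went from 48.0 ± 0.55 to 297 ± 23 (2.63), and Col12a1 (3.80) and Col7a1 (1.37) also rose. Of 35 matrix glycoproteins, proteoglycans and crosslinkers 20 were higher (21 adjusted over the list alone), 8 lower and 7 not called, median 0.43 (camera adjusted p = 0.0143, adjusted p = 0.184 with an estimated correlation). The elastic fibre gene Fbln5 rose from 18.7 ± 0.62 to 151 ± 5.8 (3.02), and Mfap5 (3.78) and Lamc1 (1.82) rose, while the small proteoglycan gene Dcn fell from 270.1 ± 1.2 to 34.6 ± 2.8 (-2.97). Dcn was uneven among control cells, at 1044 raw CPM in cluster 6 against 100 in all other cells. The TGF-beta list had 10 members higher and 3 lower, Tgfbi (-1.83), Ltbp3 (-0.39) and Tgfb1 (-0.35), among 14, with a median of 0.59 (camera adjusted p = 0.0214, adjusted p = 0.2 with an estimated correlation). Its increases included the latent TGF-beta binding protein genes Ltbp2 (1.74) and Ltbp1 (56.4 ± 2.1 to 144 ± 2.1, 1.35) and Tgfb3 (0.91). Metalloproteinases and inhibitors were split, 8 higher and 8 lower of 18 (adjusted p = 0.837), the median (0.14) being above 0 while the mean (-0.47) and the test were below it. The gelatinase genes Mmp2 (61.2 ± 0.82 to 10.9 ± 0.76, -2.49) and Mmp9 (-4.70) fell, as did Adamts9 (-2.06) and the collagenase gene Mmp13 (-3.09), which was not called against control cluster 3 (0.20) or 6 (0.73) alone. Mmp9 too was mostly in control cluster 6, at 98.2 raw CPM against 1.74 in all other cells, and was lower by -2.94 against cluster 3 and -2.10 against cluster 5.

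**Figure D2:**
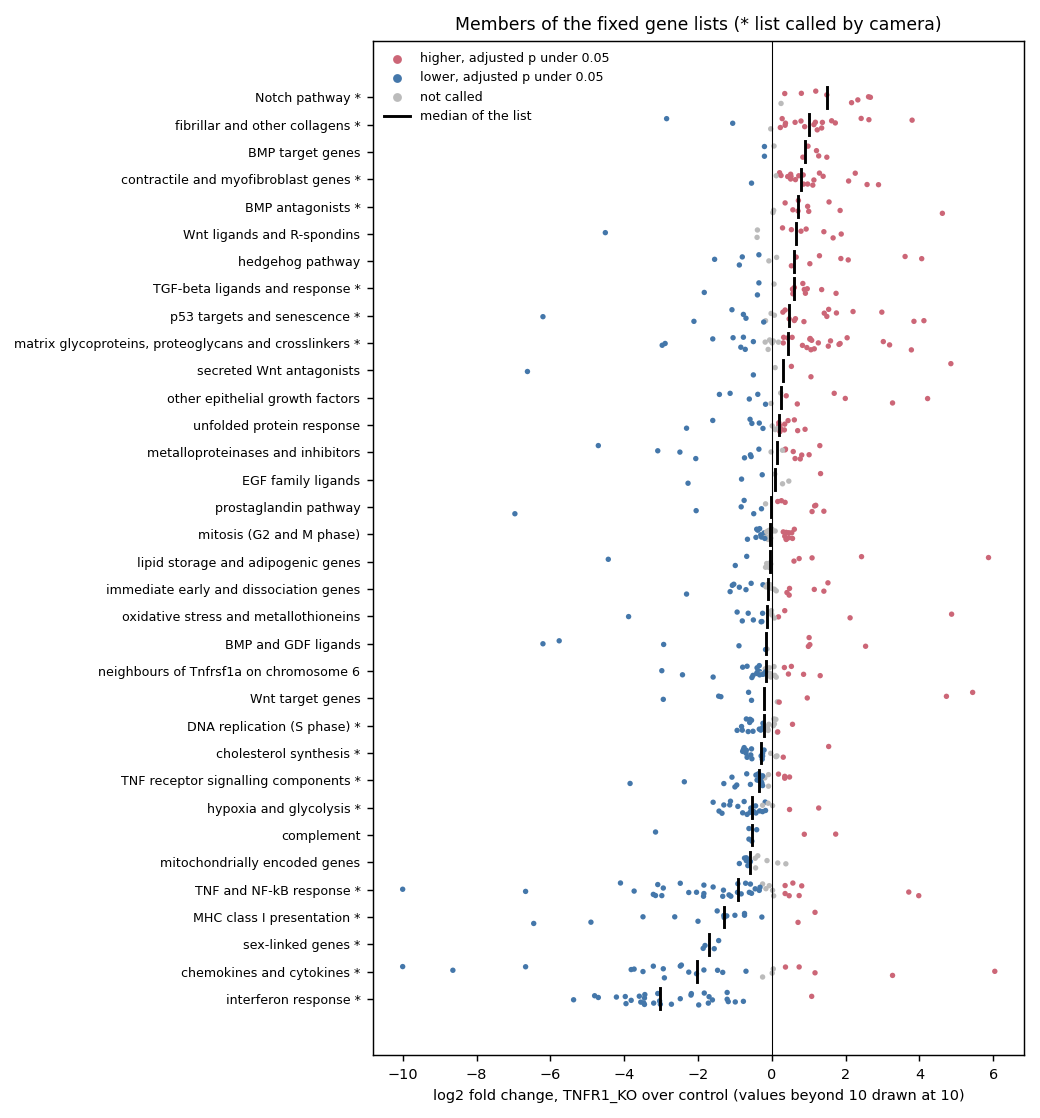
Log2 fold change of TNFR1_KO over control for the members of each gene list, with a point for each gene coloured as higher, lower or not called, a black mark for the list's median and a star for lists called by camera. The median of the interferon response is -3.03 and that of the Notch pathway 1.49.

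Several secreted signals that act on the epithelial niche were higher, and their lists were mostly not called. Of 10 Wnt ligands and R-spondins 7 were higher, 1 lower (Wnt10b; 2 adjusted over the list alone) and 2 not called, with a median of 0.66, and camera did not call the list (adjusted p = 0.0689). It was called higher in 6 of 24 other settings, among them those without S and G2M cells (adjusted p = 0.0154), with each cell scaled (0.0189) and against control cluster 3 (median 1.04, 0.0186) or 6 (1.39, 0.00341), though not against cluster 5 (0.55, 0.0931). These 4 calls were lost with an estimated correlation (adjusted p = 0.23, 0.249, 0.194 and 0.149). Rspo3, which amplifies Wnt signalling in crypt stem cells, rose from 7.30 ± 0.47 to 23.2 ± 0.28 (1.66), Wnt5a from 21.3 ± 0.29 to 40.5 ± 3.1 (0.93), Wnt4 by 1.88 and Rspo2 by 1.41. Of 6 secreted Wnt antagonists Sfrp1 (4.85), Sfrp2 (1.06) and Dkk3 (0.53) were higher and Dkk2 (-0.50) and Sfrp4 lower, Sfrp4 with 222 UMIs in controls and 2 in TNFR1_KO (median 0.31 and test up, mean -0.10, adjusted p = 0.45). Of 10 Wnt target genes Nkd2 (5.44), Rnf43 (4.73), Lef1 (0.96) and Ccnd1 (0.20) were higher and Tcf7 (-2.94), Nkd1 (-1.44), Apcdd1 (-1.38), Myc (-0.63) and Znrf3 (-0.55) lower (median -0.20 and test down, mean 0.45, adjusted p = 0.754). BMP antagonists, which hold back differentiation signals near crypts, were called higher: 9 of 11 rose, none fell and 2 were not called (median 0.72, camera adjusted p = 0.00131, adjusted p = 0.168 with an estimated correlation). Fst rose from 25.5 ± 1.8 to 74.8 ± 4.0 (1.55), Fstl1 from 130.3 ± 2.2 to 256 ± 5.9 (0.97), and Nbl1 (1.85) and Nog (4.62) rose. The 10 BMP and GDF ligands were mixed (median -0.15 and mean -1.05, with camera down and fry up, adjusted p = 0.885). Inhbb (2.54), Bmp4 (1.03), Bmp2 (1.01) and Bmp1 (0.99) were higher and Gdf15 (-6.20), Gdf10 (-5.76), Bmp6 (-2.93), Gdf11 (-0.89) and Inhba (-0.17) lower. Bmp4 turned to -0.35 against control cluster 5 alone. Of 8 BMP target genes Id4 (1.49), Smad9 (1.27), Smad6 (1.21), Id2 (0.98) and Id1 (0.84) were higher and Id3 (-0.20) and Smad7 (-0.20) lower (median 0.91, adjusted p = 0.0635). The list was called higher in 4 of 24 other settings: without control replicate 2 (adjusted p = 0.0444), without the low count filter (0.0249), against control cluster 6 (0.00506) and with fry (2.03e-05). With an estimated correlation the first 3 calls were lost (adjusted p = 0.254, 0.154 and 0.149).

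The Notch pathway was called higher, with 8 of 9 genes up, none down and 1 not called (median 1.49, camera adjusted p = 0.00158, adjusted p = 0.168 with an estimated correlation). The receptor genes Notch1 (2.62) and Notch3 (2.16), the target Hes1 (20.1 ± 1.6 to 45.9 ± 2.2, 1.19) and the ligand gene Jag1 (0.80) rose. The hedgehog list was not called (8 higher, 4 lower of 14, median 0.59, adjusted p = 0.151), although its transcription factor genes Gli1 (3.61) and Gli2 (1.87) and the co-receptor gene Boc (2.07) rose. Gas1 (-0.88), Foxf2 (-0.80), Foxl1 (-1.55) and Sufu (-0.35) were lower. Among 7 EGF family ligands 1 was higher, Ereg (1.32), and Btc (-2.27), Areg (-0.82) and Hbegf (-0.26) were lower (median 0.08, mean -0.17 and test down, adjusted p = 0.754). Hbegf was not called with each cell scaled to the same total (-0.17) or against control cluster 5 alone (-0.04). Of 13 other growth factors for epithelium, 6 were higher and 5 lower (median 0.24, adjusted p = 0.466). Pleiotrophin, encoded by Ptn, rose from 977 ± 13 to 3891 ± 198 (1.99), and Il11 (3.27) and Fgf2 (1.69) rose, while Fgf10 (-1.42), Fgf7 (127 to 57.9, -1.13), Angpt1 (-0.61), Hgf (-0.38) and Vegfa (-0.17) fell. Of 14 prostaglandin pathway genes 7 were higher and 6 lower (median -0.01, mean -0.42, adjusted p = 0.885), with the synthase gene Ptges down (-0.83), the receptor genes Ptgfr (1.09) and Ptger1 (1.19) up, and Ptger2 at 164 UMIs in controls and 1 in TNFR1_KO.

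Genes of DNA replication were lower and p53 targets higher. Of 26 S phase genes 15 fell, 2 rose (Rrm2, 0.56, and Wdr76, 0.16) and 9 were not called (median -0.21, camera adjusted p = 0.0184, adjusted p = 0.395 with an estimated correlation). Fen1 (41.5 ± 0.79 to 23.5 ± 0.98, -0.82), Ung (-0.94), Chaf1b (-0.80) and Cdc45 (-0.69), all used in copying or repairing DNA, fell. Mitosis genes were split, 10 higher and 9 lower of 30 (median -0.04, mean 0.02 and test up, adjusted p = 0.916), with Cenpf (0.61), Ndc80 (0.56), Ccna2 (0.46) and Kif23 (0.54) up. The list was called in opposite directions by setting, lower without S and G2M cells (adjusted p = 2.57e-04) and against control cluster 6 (17 lower, 5 higher, adjusted p = 0.0244), and higher in cells below 10000 UMIs (15 higher, 3 lower, adjusted p = 0.00493). With an estimated correlation the 3 calls were lost (adjusted p = 0.242, 0.503 and 0.186). Without S and G2M cells Cenpf (0.12) and Ccna2 (0.01) were not called, nor was Kif23 (0.04) against control cluster 6. Of 23 p53 targets and senescence genes 14 rose, 6 fell and 3 were not called (median 0.47, camera adjusted p = 0.0289, adjusted p = 0.179 with an estimated correlation). The cell cycle inhibitor gene Cdkn1a rose from 14.1 ± 0.35 to 111 ± 4.8 (2.98), and Igfbp3 (4.12) and Ccng1 (1.75) rose, while Gdf15 fell. By phase scores, 50.7% ± 0.1 of control and 32.5% ± 0.84 of TNFR1_KO cells were called S, 30.5% ± 0.4 and 29.8% ± 0.89 G2M, and 18.8% ± 0.35 and 37.7% ± 0.64 G1. Thinned to 5000 UMIs the shares were 50.5% ± 0.43 and 32.5% ± 1 in S, 25.5% ± 0.33 and 25.7% ± 0.8 in G2M, and 24.1% ± 0.64 and 41.9% ± 0.72 in G1. Before thinning, 44.8%, 46.1% and 43.5% of cells in control clusters 3, 5 and 6 were called S, and 30.7% in TNFR1_KO cluster 1. In the shallow clusters 2, mostly control, and 4, mostly TNFR1_KO, 59.1% and 40.3% were called S, so these raised the share of each genotype. Free RNA can enter these calls and stays open, and no cycling is read from phase calls alone.

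Glycolysis and sterol genes were lower. Of 24 hypoxia and glycolysis genes 19 fell, 2 rose (Adm, 1.27, and Pfkfb3, 0.48) and 3 were not called (median -0.54, camera adjusted p = 6.96e-04, adjusted p = 0.179 with an estimated correlation), with the hexokinase gene Hk1 (53.7 ± 0.78 to 24.7 ± 0.47, -1.12), the phosphofructokinase gene Pfkl (-1.43) and Ndrg1 (-1.30) down. Of 20 cholesterol synthesis genes 14 fell, among them Fdft1 (137 ± 2.9 to 80.7 ± 5.2, -0.77), Stard4 (-0.79) and Lss (-0.75), and Msmo1 (0.31) and Sc5d (0.14) were among those that rose, with 3 not called (median -0.28, camera adjusted p = 0.0277, adjusted p = 0.179 with an estimated correlation). The unfolded protein response was not called (12 higher, 6 lower of 21, median 0.19 and test up, mean -0.04, adjusted p = 0.472). Its chaperone genes Pdia6 (0.90) and Pdia4 (0.70) rose and its regulator genes Atf3 (-2.31) and Ern1 (-1.60) fell. Of 14 lipid storage and adipogenic genes Cebpa (5.87), Plin4 (2.43), Apoe (1.09), Lpl (0.74) and Pdk4 (0.60) rose and Angptl4 (-4.43), Pparg (-0.99) and Cebpd (-0.68) fell (median -0.05 and test down, mean 0.29, adjusted p = 0.997). Oxidative stress genes and metallothioneins were not called (4 higher, 8 lower of 16, median -0.13, mean 0.00, adjusted p = 0.321), with Gsta4 (2.12), Cat (0.35), Gclc (0.18) and Gpx3, at 0.148 ± 0.060 CPM in TNFR1_KO, up, and Sod3 (-3.88), Slc7a11 (-0.94) and Txnrd1 (-0.80) down. Immediate early genes were not called (6 higher, 8 lower of 23, median -0.11, adjusted p = 0.466), with Klf2 up (1.41) and Hspb1 (-1.07) and Hspa1b (-1.03) down.

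Of 13 mitochondrially encoded genes 7 were lower (6 adjusted over the list alone) and none higher (median -0.58, adjusted p = 0.136), among them mt-Atp6 (-0.88), mt-Co1 (-0.69), mt-Cytb (-0.60) and mt-Co2 (-0.58). In cells below 10000 UMIs none of these 4 was called (-0.38, -0.01, -0.15 and -0.11). Those cells were mostly of control cluster 2 and TNFR1_KO cluster 4. These clusters had median mitochondrial shares of 0.059% and 0.0976%, so that setting says little about mitochondrial genes. Against control cluster 5 mt-Co2 was not called (-0.36). The list was called lower in 5 of 24 other settings: against clusters 3 (median -0.77, adjusted p = 0.0311) and 6 (-0.62, adjusted p = 0.0474), without S and G2M cells (0.0458), with limma-voom (0.0138) and without TNFR1_KO replicate 5 (0.00488). All 5 calls were lost with an estimated correlation (adjusted p = 0.664, 0.64, 0.645, 0.602 and 0.537). The TNFR1_KO mice spread widely, with mt-Atp6 at 1724, 3498 and 2569.5 in replicates 4, 5 and 6. The 35 tested genes near Tnfrsf1a on chromosome 6 were not called as a list (5 higher, 16 lower, median -0.17, adjusted p = 0.093), though they were called lower in 3 of 24 other settings, without the low count filter and against control cluster 5, both lost with an estimated correlation (adjusted p = 0.36 and 0.358), and with fry. Tpi1 (-0.79) and Cdca3 (-0.67) were lower there, and Scnn1a (1.31), Cd27 (0.86), Spsb2 (0.53), Iffo1 (0.45) and Eno2 (0.34) higher. The sex-linked list fell, all 4 tested genes being Y-linked (median -1.69, camera adjusted p = 0.0029, adjusted p = 0.179 with an estimated correlation). Ddx3y went from 29.5 ± 0.78 to 10.9 ± 0.76 (-1.44), Eif2s3y from 22.8 ± 1.1 to 6.50 ± 0.27 (-1.81), Kdm5d by -1.86 and Uty by -1.56. Their summed level in raw CPM was 3.67 ± 0.65 in control cluster 6, against 63 ± 1.3 in control cluster 3, 85.3 ± 6.2 in control cluster 5 and 19.7 ± 1.7 in TNFR1_KO cluster 1. Cluster 2 held 63.6 ± 1.2 in controls and 39.7 ± 24 in TNFR1_KO, where the 56, 82 and 60 cells of the mice gave 14.1, 61 and 43.8.

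**Figure D3:**
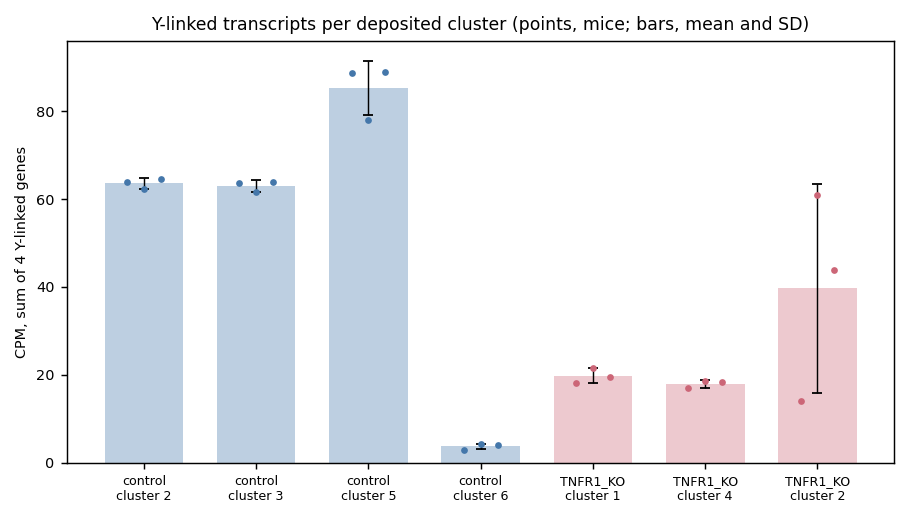
Summed raw CPM of 4 Y-linked genes by deposited cluster and genotype, with 1 point per mouse and bars for mean and SD (n = 3). Control cluster 6 lies at 3.67 ± 0.65 and TNFR1_KO cluster 1 at 19.7 ± 1.7, below control clusters 3 and 5.

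The deposited clusters were almost entirely of 1 genotype. Cluster 1 held 79.4% ± 2.1 of TNFR1_KO cells and no control cell, and clusters 3, 5 and 6 held 33.9% ± 1.3, 19.2% ± 2.2 and 9.23% ± 0.67 of control cells with 1 TNFR1_KO cell between them. Cluster 2 held 37.5% ± 2 of control and 1.13% ± 0.35 of TNFR1_KO cells, and cluster 4 held 0.138% ± 0.06 and 19.5% ± 2.3. From 96.9% to 100% of a cluster's cells came from 1 genotype, each two-sided exact permutation p was 0.1, the smallest that 3 mice against 3 allow, and the sizes are described here without being read as a shift of cell types. The genes that led the clusters, given only to identify them, were Meg3, Rpl39l, Mgp and Mfap2, among others, for cluster 1, Spp1, Cxcl10, Cck, Slpi and Enpp2 for cluster 3, Gm4788, Smim1, Tmem151a, Frmd4b and Myrf for cluster 5, and Mmp9, Traf1, Fyb, Fam19a1 and Crabp1 for cluster 6. Lars2 and AY036118 led both cluster 2, followed by Gm42418, Hist1h1b and Hist1h2ab, and cluster 4, followed by Fhl1, Krt19 and Tagln. Clusters 2 and 4 stood apart in quality, with medians of 4574 and 4908 UMIs and 0.059% and 0.0976% mitochondrial UMIs per cell, against 30388 to 43928 UMIs and 1.33% to 2.56% in the others. Of their cells 87% and 81.6% lay below 10000 UMIs, against 0.469% to 0.786% in the others. Every result in cells below 10000 UMIs is thus mostly control cluster 2 against TNFR1_KO cluster 4.

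**Figure D4:**
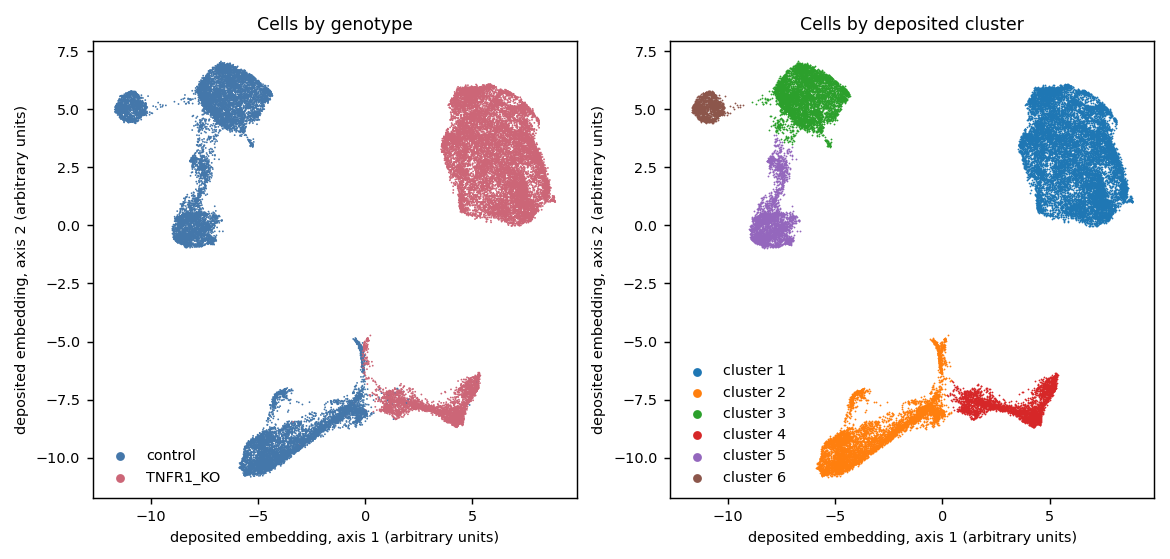
Deposited embedding of all cells, in arbitrary units on both axes, coloured by genotype and by deposited cluster number, with 1 point per cell. Cells of the genotypes lie apart, and the larger genotype makes up 96.9% to 100% of each cluster.

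The list changes were also measured against each large control cluster by itself, in a comparison chosen after the data were seen. Against TNFR1_KO cluster 1, the interferon list was lower than in control cluster 3 (median -3.26), cluster 5 (-2.63) and cluster 6 (-2.14), and camera called each at the preset correlation. With an estimated correlation no list was called against any of the 3 clusters, in cells below 10000 UMIs or in any other of 22 settings. The adjusted p of the interferon list was then 0.135, 0.228 and 0.16, that of TNF and NF-kB 0.135, 0.358 and 0.149, and that of contractile genes 0.135, 0.228 and 0.149. The TNF and NF-kB list was lower in TNFR1_KO by -0.74, -0.50 and -1.25, and contractile genes were higher by 0.79, 0.80 and 0.97. MHC class I presentation was called against clusters 3 (-1.42) and 6 (-1.52) and not against cluster 5 (-0.63, adjusted p = 0.0709), and with an estimated correlation the first 2 calls were lost (adjusted p = 0.322 and 0.202). Whether these values differ between clusters was not tested. The Y-linked genes turned direction, being lower than in clusters 3 (-1.68) and 5 (-2.02) and higher than in cluster 6 (2.73). Other named genes were called in the other direction, Pparg against clusters 3 (0.49) and 6 (2.61), Areg (0.32) against cluster 5, and Jag1 (-0.26), C1ra (0.68), Cenpf (-0.36) and Hspb1 (0.40) against cluster 6. Gas1 (0.11) and Hspa1b (0.07) against cluster 5 and Slc7a11 (0.16) against cluster 6 were not called. Other lists lost their call against cluster 3 with medians close to those of all cells (matrix genes 0.48, TGF-beta 0.51), as did TGF-beta (0.52) and S phase (-0.24) against cluster 5 and Notch against cluster 6 (1.47), while the medians of cholesterol synthesis against cluster 5 (-0.19) and of glycolysis against cluster 6 (-0.20) were smaller. Besides those named above, lists not called over all cells were called against cluster 6, among them secreted Wnt antagonists (median 3.51), BMP targets (1.56), other growth factors (0.61) and the unfolded protein response (0.42), all higher, and against cluster 5 the neighbours of Tnfrsf1a (-0.40), lower. With an estimated correlation their adjusted p was 0.202, 0.149, 0.202, 0.202 and 0.358. In cells below 10000 UMIs the Notch (0.80) and p53 (0.31) lists were not called, immediate early genes were called lower (-0.27, lost with an estimated correlation, adjusted p = 0.204), Id2 (0.01), Ptges (-0.16), Pparg (-0.52) and Slc7a11 (-0.52) were not called, and Hbegf (0.98) and C1ra (1.03) were higher.

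**Figure D5:**
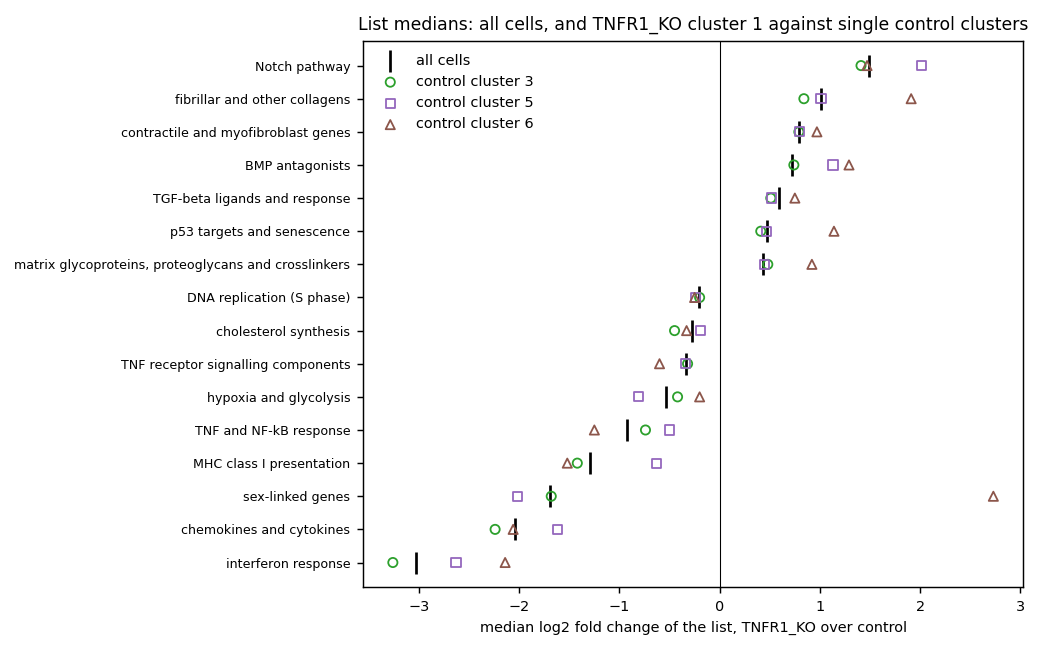
Median log2 fold change of gene lists in TNFR1_KO cluster 1 against control cluster 3, 5 or 6, with an open symbol for each list and cluster and a black mark for all cells. The interferon response lies at -3.26, -2.63 and -2.14.

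Within deposited cluster 2, whose cells were shallow in both genotypes, Meg3 rose from 0.279 ± 0.31 to 639.9 ± 27 CPM (log2 fold change 11.20, edgeR adjusted p = 6.15e-21), Col6a3 from 16.7 ± 3.6 to 975 ± 121 (5.89) and the matrix gene Fbln2 from 95.0 ± 10 to 1311 ± 211 (3.80). Oaz1, a regulator of polyamine synthesis, fell from 1388 ± 10 to 138 ± 9.4 (-3.34), Mif, a cytokine gene, from 3435 ± 128 to 427 ± 31 (-3.01) and Arhgdib by -4.44. Of 10495 genes 3411 were higher and 3435 lower, and 3672 of these were called in the same direction over all cells. The TNFR1_KO side rested on 56, 82 and 60 cells with 250874 to 459167 UMIs per mouse, whose median mitochondrial share was 6.31%, 16.6% and 15.8%, against 0.0546% to 0.0582% in the 1895, 2017 and 2328 control cells, so cells of unlike quality were compared.

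Markers of smooth muscle or myofibroblasts were higher in TNFR1_KO (9 of 10 tested, none lower), as were 6 of 10 of fibroblasts, among them Col1a1 (719 ± 6.6 to 1108 ± 38, 0.63), with Dcn lower. Of 8 tested pericyte markers 6 were higher, among them the channel genes Kcnj8 (0.108 ± 0.035 to 12.7 ± 1.5, 6.90) and Abcc9 (6.64), Mcam (3.72) and Pdgfrb (18.1 ± 1.2 to 51.8 ± 6.8, 1.51), and Rgs5 (-2.55) and Ndufa4l2 (7.81 ± 0.52 to 0.103 ± 0.064, -6.22) were lower. Control cluster 5 carried most of the Ndufa4l2 level, at 22 raw CPM against 0.438 in all other cells. Of 9 trophocyte markers 6 were higher and 3 lower (C3, Pi16, -0.56, and Cd34, -0.25), and of 6 telocyte markers F3 (1.88), Wnt4 and Wnt5a were higher and Foxl1 lower. Of 8 mesothelial markers 7 were lower, among them Upk3b (4.79 ± 0.39 to 0.0103 ± 0.0072, -8.76) and Cldn15 (-2.68), and Krt19 was higher (1.17 ± 0.039 to 9.57 ± 1.5, 3.03). All 4 tested neuronal markers were lower, Tubb3 (-1.23), Uchl1 (-1.30), Stmn2 (-3.96) and Elavl4 (no UMI in TNFR1_KO, at least 50.1-fold), and of the glial ones Ncam1 (1.27) was among those higher and Cdh19 was lower (no UMI in TNFR1_KO, at least 41.0-fold). Kdr (3.75), Flt1 (1.98) and Egfl7 (0.39) were higher and Plvap lower (-0.94) among 6 endothelial markers, and Etv1 (1.19) was higher and Gja1 (-1.14) lower among 3 markers of interstitial cells of Cajal. Of 3 tested epithelial markers Krt19, which is also on the mesothelial list, was higher as given there, and Krt8 and Krt18 were lower, Krt18 going from 1.24 ± 0.39 CPM to no UMI, at least 208-fold lower, with Epcam at no more than 0.0322 CPM in any mouse. Of 6 tested myeloid markers Lyz2 was higher (0.0344 ± 0.023 to 2.23 ± 0.19) and Cd14 (-1.57), Cd74 (-2.14), Cd68 (-0.68) and Csf1r (-0.68) were lower, with Ptprc at no more than 0.0124 CPM. Of mast cell markers 1 was tested, Hdc (-1.09), none of the lymphocyte or red blood cell markers could be tested, and of 12 cycling markers 4 were higher (Cenpf, Nusap1, Ccnb2 and Tpx2) and 4 lower (Cdk1, Ccnb1, Top2a and Mcm5).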

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

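Choices of design, lists and most alternatives were fixed before the data were examined, whereas the alternatives without clusters 2 and 4, above or below 10000 UMIs, against single control clusters, with an estimated correlation within every other setting, and with a 1.5-fold threshold were chosen after seeing the data. Tnfrsf1a stayed lower and past the threshold under every alternative run (log2 fold change -2.80 against control cluster 5 to -1.46 against cluster 6). Against 5253 genes higher and 5209 lower, a mean of at least 10 CPM left 2604 and 2623, as fewer genes were tested, cells below 10000 UMIs gave 2967 and 2860, and testing for a change above 1.5-fold gave 1951 and 1875, since that test asks for more. The cause of the lower counts in the shallow cells, which were mostly control cluster 2 and TNFR1_KO cluster 4, was not tested. Scaling each cell to the same total gave 4058 higher and 5280 lower, a share of 43.5% higher in place of 50.2%. Without clusters 2 and 4 the counts were 5218 and 5154, and thinned to the smallest library they were 5102 and 5002. Leaving out each mouse gave 4793 to 5636 higher, 4755 to 5692 lower, -2.39 to -2.33 for Tnfrsf1a, 16 to 17 lists, 5014 to 6287 genes in cluster 2 and 6 to 6 cluster shares called. Of 16 lists called, 0 were called with an estimated correlation (8 at an unadjusted p under 0.05), a test with little power on 6 libraries, and fry called 28. The 6 deposited clusters became 18 at Leiden resolution 1.0, all called. The other clusterings gave 8 or 9, all called, but clusters with over 95% of cells from 1 genotype then held 84.3% and 84.2% of cells at resolutions 0.3 and 0.5, 90.9% at 1.0 and 72.1% with genes centred within each mouse, against 100% in the deposited clusters. Centring put 5316 cells of deposited cluster 2 and 2590 of cluster 4 in 1 cluster. Of the named genes, some were called in the other direction, for reasons that were not tested. In cells below 10000 UMIs these were Hbegf (0.98) and C1ra (1.03), against control cluster 3 Pparg (0.49), and against cluster 5 Bmp4 (-0.35) and Areg (0.32). Against cluster 6 they were Jag1 (-0.26), C1ra (0.68), Cenpf (-0.36), Pparg (2.61), Hspb1 (0.40), Eif2s3y (2.15), Ddx3y (2.79), Kdm5d (2.68) and Uty (2.96). On the other side of 0 and not called were Mmp13 against clusters 3 (0.20) and 6 (0.73), Gas1 (0.11) and Hspa1b (0.07) against cluster 5 and Slc7a11 (0.16) against cluster 6. Lists called numbered 16 against control cluster 3, 13 against cluster 5 and 21 against cluster 6. With an estimated correlation 0 were called in each of 22 settings, so every gain below was lost except those with fry. Calls were lost for TGF-beta at 10 CPM and against clusters 3 (median 0.51) and 5 (0.52), matrix genes against cluster 3 (0.48), Notch against cluster 6 (1.47) and in cells below 10000 UMIs (0.80), S phase (-0.24), MHC class I (-0.63) and cholesterol synthesis (-0.19) against cluster 5, the last also without S and G2M cells and with each cell scaled, p53 targets in cells below 10000 UMIs (0.31) and glycolysis against cluster 6 (-0.20). Calls were gained for Wnt ligands and R-spondins in 6 of 24 settings, mitochondrial genes in 5 (without TNFR1_KO replicate 5, 0.00488), BMP targets in 4 (without control replicate 2, 0.0444) and the neighbours of Tnfrsf1a in 3. Against cluster 6 they were gained for secreted Wnt antagonists (adjusted p = 0.0359), BMP targets (0.00506), other growth factors (0.0256) and the unfolded protein response (0.00508). Mitosis genes were called lower against cluster 6 and without S and G2M cells and higher in cells below 10000 UMIs. No paired analysis was possible because the genotypes share no mouse number. Removal of doublets was void, since 1 cell was marked. The difference of effects between clusters and alternatives to the defining genes of clusters were not run, because cluster 1 held no control cell and the deposited clusters were used. Genes near the floor, such as Sfrp4 and Ptger2, are limited by depth.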

Other observations

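Some of the tests below were chosen only after the result was seen. They were the tests of depth for Y-linked transcripts, Xist, a common pool, single control clusters and Tnf, and the counts of splits. The tests of chromosome dosage and of joint detection of Y-linked genes were chosen before the result was seen. Thinning to the smallest total was among the alternatives fixed before the data were examined.

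Genotype differences were spread unevenly over chromosomes. The median log2 fold change was -0.54 over 707 genes of chromosome 10 and -0.49 over 605 genes of chromosome 15, and it was 0.36 over 831 genes of chromosome 9, 0.33 over 713 of chromosome 17 and 0.32 over 522 of chromosome 12. Differences between chromosomes made up 3.45% of the variance of log2 fold changes. Control clusters 3, 5 and 6 also differed from one another by chromosome, with an SD of chromosome medians of 0.106 over 19 autosomes and 5279 genes, against at most 0.019 in 200 shuffles of gene positions. Chromosome copy number was not measured.

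Y-linked transcripts were near 0 in control cluster 6 and lower in TNFR1_KO, which no group in the labels names, though TNFR1_KO cluster 2 varied between mice (14.1, 61 and 43.8 CPM from 56 to 82 cells). Shallower sequencing of cluster 6 is argued against, since in each control mouse its Y-linked CPM was 4.6% to 6.69% of that in cluster 3, a measure already scaled to depth. Female cells are argued against by Xist, at 0 CPM in control cluster 6 of every mouse. In TNFR1_KO cluster 1 Xist was at 0.0115, 0.0396 and 0.00634 CPM in replicates 4, 5 and 6. A candidate explanation is loss of the Y chromosome in part of the cells: in TNFR1_KO cluster 1 the median odds ratio of joint detection over 6 pairs of Y-linked genes was 7.67, against 0.85 to 1.38 in 1000 matched sets of autosomal genes, and it was 2.19 in control cluster 3 and 1.68 in control cluster 5. Genotype is argued against for the level in control cluster 6, since clusters 3 and 5 of the same mice were at 63 ± 1.3 and 85.3 ± 6.2 CPM against 3.67 ± 0.65, while for the lower level in TNFR1_KO it stays open and was not tested, and silencing of the chromosome was not tested for either.

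Most genes were called, and mice of 1 genotype differed little. Unequal totals between libraries are argued against, as 10104 genes were called after thinning to the smallest total. That total was still 119132056 UMIs, so the depth shared by all libraries was not tested as a cause. Direct shifts of whole chromosomes as the whole cause are argued against too. After the median of each chromosome was taken out, 9723 genes were called, 8103 of them in the same direction as before. This takes out only a shift common to a chromosome's genes, and such shifts made up only 3.45% of the variance of log2 fold changes. Dosage of parts of a chromosome and indirect effects of dosage were not tested. A candidate explanation for the small spread of the control mice is 1 pool of cells behind their libraries, or cultures that shared their founders. The chromosome profiles of clusters 3, 5 and 6 correlated across autosomes at 0.990 to 0.998 between control mice, over 9 correlations. Each profile was taken against the mouse's own mean over these clusters, which removes differences between mice. The correlations were not compared with shuffled gene positions, so they cannot tell a pool from separate cultures. Cell states that use the same genes in every mouse might give such profiles too and were not excluded, and no such test was run for the TNFR1_KO mice, whose libraries lay further apart (median absolute log2 ratio between mice 0.106 to 0.213, against 0.0637 to 0.0782). The genotype itself and any other difference between the cultures stay open and were not tested apart.

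The interferon response list was lower in TNFR1_KO. A single control cluster with high interferon genes is argued against, as the median was -2.14 or lower against each of clusters 3, 5 and 6. Once chromosome medians were taken out, the list's median was -2.87, with 31 of 32 genes lower. That outcome was fixed in advance, since autosome medians ran only from -0.54 to 0.36, against -3.03 for the list. Direct chromosome-wide shifts of that size are too small for the change, and indirect effects of dosage were not tested. Whether TNF made by the cultured cells might drive the difference cannot be told apart from other sources, with 4 UMIs of Tnf over the 3 control mice, since serum, Matrigel and protein were not measured. The genotype and any other difference between the cultures stay open and were not tested apart.

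The 6 mice make 10 splits into 3 and 3, too few for a share under 0.05. Over all cells 1 split, the real one, gave as many genes (10462, the highest other 0), 1 gave as many lists (16, the highest other 14), and within cluster 2 1 gave as many genes (6846, the highest other 0). Every other split mixes the genotypes, which puts most of their difference into the spread within groups. The counts of 0 genes follow from that and lend no support. Camera at the preset correlation still called up to 14 lists in mixed splits. The groups of a mixed split hold unequal numbers of each genotype, so part of the genotype difference stays between them. These counts of lists are therefore no rate of false calls, and they neither support nor weaken the list calls above.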
